A study of Mus musculus with 6 samples.

How the data were processed

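The series holds expression arrays of quadriceps RNA from 6 mice, 3 with a single nebulin allele and 3 wild type. Per the labels' protocols, RNA was isolated with Trizol and a Qiagen column kit, and biotin-labelled cRNA was prepared by the standard Affymetrix procedure. The labels name each sample as a separate mouse. The deposited values are on a log2 scale, 1 column per array, and the sorted columns were identical (largest difference 0), as quantile normalization leaves them. The software that summarised the probes, its background correction and the version of its probe definition are not given in the sources used here. No per-sample column was left unused. Since each array was forced to one distribution, a shift of all transcripts together would not be seen, and the brightest probe sets can hold tied values: 4 had a single value on all 6 arrays.

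The table has 16556 entries, of which 64 are control probe sets and 16492 gene probe sets. The platform annotation names 15270 of these with 1 gene symbol each, and 1222 are unnamed here. All 15270 Entrez identifiers were found in a RefSeq gene table of assembly GRCm38.p6, which was used for symbols and for the order of genes beside Neb only. The genome build behind the probe sets is not given in the sources used here, so no coordinates are printed. Probe sets were tested if their mean over all 6 arrays was above the 30th percentile of gene probe sets, 6.74 on the log2 scale, which left 11544, of which 10850 are named. Cross-hybridisation between related genes, such as the myosin heavy chains, was not assessed.

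Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no array weights), as heterozygous minus wild type, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Errors of differences are limma's SE, errors of group means are SD, and intervals are at 95%. Neb was also compared by an exact two-sided permutation test. Gene lists were compared with camera at a preset inter-gene correlation of 0.01, over 10849 genes with 1 probe set each, the brightest, and lists with fewer than 3 measured members were not tested. The same lists were run with the correlation estimated per list and with the directional test of fry.

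The design, the alternatives, 31 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover nemaline myopathy genes, the thin filament, fast and slow fibre genes, Z-disc genes, stretch responses, atrophy, regeneration, calcium handling, glycolysis, fatty acid oxidation, oxidative phosphorylation, the tricarboxylic acid cycle, ribosomal proteins, the proteasome, chaperones, immediate early genes, the clock, extracellular matrix, growth signalling, neuromuscular junction genes, genes beside Neb, interferon responses, and markers of fibroblasts, leukocytes, adipocytes, endothelium, smooth muscle, red cells, nerve and tendon. The rule named Neb, sex-linked genes, up to 10 genes per direction with the largest difference among those that passed, and the 2 members of each list with the smallest p. Other list members were named after their values were seen, among them Myl2, Myl3, Per1, Nfil3, Tef, Nr1d1, Mt1, Cdkn1a, Klf4, Zfp36, Ier3, Pdk4, Angptl4, Ankrd2, Trim63, Fbxo32, Fos, Egr1, Loxl1, Myh7b and Acta1.

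Mice of both groups carry the numbers 1 to 3, and the labels do not say that a number stands for a shared litter or day. The deviations of same-numbered mice from their group means correlated at 0.187, 0.234 and 0.129, all above the limit of 0.1 set for pairing, while differently numbered mice gave -0.168 to -0.039. Deviations from a group mean cancel out within the group, so the negative values follow from the positive ones and add no evidence. A pairing by number thus rests on the same-numbered correlations alone and is uncertain. The main fit leaves the mice unpaired, and values with the number as a block are given where they change a call.

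No 2 arrays were copies of each other: 25 to 56 probe sets had identical values in any pair. None of the 64 control probe sets passed the threshold, and 7 had an unadjusted limma p under 0.05. The 3' to 5' log2 differences of the beta-actin controls were 0.33 ± 0.06 in heterozygous and 0.39 ± 0.02 in wild-type mice (SD, n = 3 each; exact permutation p = 0.2). Those of the Gapdh, pyruvate carboxylase and transferrin receptor controls gave exact p of 1, 0.2 and 0.2.

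The fit was tested on simulated data of the 11544 probe sets. It recovered 72% of probe sets given a log2 difference of 0.3, 82% of those given 0.5 and 100% of those given 1 or 2, with 6 false calls, and made 0 calls when nothing was changed. For lists over 10849 genes, a list raised by 0.3 had an adjusted p of 1.92e-07 with camera, 0.106 with an estimated correlation and 0.0121 with fry. Noise was drawn independently for each probe set, so the genes of a list were uncorrelated in the simulation. In the data the same list, of slow fibre genes, had an estimated correlation of 0.36. The simulation therefore does not show how the list tests behave with correlated genes. Alternatives were no filter, a filter at the 50th percentile, quantile normalization, median centring, the replicate block, an intensity trend, array weights, a test with the spread of each probe set taken alone and unequal between groups, an adjusted p of 0.1, the mean of all probe sets of a gene and leaving out each mouse in turn. Cyclic loess was added after seeing the data.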

Results

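Messenger RNA was measured in the quadriceps, a large thigh muscle, of 6 mice with Affymetrix expression arrays, 1 array per mouse. The labels give 3 mice with a single nebulin allele (heterozygous) and 3 wild-type mice, each a separate animal. Nebulin, encoded by Neb, is a giant protein that runs along the thin filament of the skeletal muscle sarcomere, and mutations in its gene are a cause of nemaline myopathy. The comparison of the 2 genotypes asks which transcripts differ in muscle when 1 copy of the gene is lost. The deposited log2 values of all arrays had the same distribution, with a median of 7.23 and a range of 5.56 to 14.81. Arrays of the same genotype correlated at r = 0.9965 to 0.9977 across probe sets, and arrays of different genotype at 0.9932 to 0.9953. The first principal component held 53.3% of the variance and placed the heterozygous mice between -8.62 and -4.74 and the wild-type mice between 5.96 and 8.25. On the second, with 16.1%, heterozygous mouse 1 lay apart at 7.59, with the other mice between -3.78 and 2.40. The female transcript Xist was dim in both groups (6.29 and 6.28), whereas the Y-linked Eif2s3y averaged 8.98 ± 0.38 in heterozygous and 9.38 ± 0.09 in wild-type mice (SD, n = 3 each). The small number of arrays limits the precision of every value given here.

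The only probe set of Neb, 17996_at, ranked 196 of 16492 gene probe sets in signal, which depends on the probes as well as on the amount of transcript. It averaged 11.92 ± 0.17 in heterozygous and 12.14 ± 0.05 in wild-type muscle (SD, n = 3 each), and each heterozygous mouse lay below each wild-type mouse. The log2 difference was -0.22 ± 0.08 (SE), 14.3% lower with a 95% confidence interval of 2.92% to 24.4%. This difference did not pass the test over all probe sets (limma, p = 0.021, adjusted p = 0.161), and the two-sided exact permutation p was 0.1, the smallest that 3 mice against 3 can give. Without heterozygous mouse 1 the difference was -0.31 and passed, at adjusted p = 0.040. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the value does not check the labels. Among the genes beside Neb on chromosome 2, 10 were tested and none passed, over all genes or adjusted over the list alone. Orc4 (log2 difference -0.10) and Tnfaip6 (0.20) had the smallest p of these, at adjusted p = 0.165 and 0.131, and the list test gave an adjusted p of 0.84.

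The largest differences between the genotypes were higher transcripts of the slow muscle fibre. Myh7, the slow myosin heavy chain, was 8.0-fold higher in heterozygous muscle (11.88 ± 0.41 against 8.88 ± 0.87, SD, n = 3 each; log2 difference 3.00 ± 0.38, SE; adjusted p = 0.0104). The slow troponin subunits followed, with Tnnc1 5.40-fold, Tnni1 5.29-fold and Tnnt1 5.17-fold higher (log2 differences 2.43 ± 0.22, 2.40 ± 0.16 and 2.37 ± 0.15; adjusted p = 0.0035, 0.0014 and 0.0014). Ddit4, a stress-induced inhibitor of mTOR signalling, was 4.73-fold higher, and the transcription factor gene Cebpd 2.97-fold (log2 differences 2.24 ± 0.29 and 1.57 ± 0.22). Also higher were Mybph, encoding a myosin-binding protein, at 2.67-fold, the connective tissue growth factor gene Ccn2 at 2.64-fold, the arrestin-domain gene Arrdc2 at 2.56-fold and the deubiquitinase gene Otud1 at 2.45-fold.

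The falls were smaller. The uncharacterised gene 1700001O22Rik was 2.00-fold lower in heterozygous muscle (7.21 ± 0.17 against 8.21 ± 0.09; log2 difference -1.0 ± 0.08; adjusted p = 0.0025). Odc1, which starts polyamine synthesis, was 1.87-fold lower, and Smox, the spermine oxidase, 1.59-fold (log2 differences -0.90 ± 0.17 and -0.67 ± 0.10; adjusted p = 0.032 and 0.015). Pfkfb3, a regulator of glycolytic flux, was 1.73-fold lower, the mitochondrial carrier gene Ucp3 1.64-fold and the lipid droplet gene Plin5 1.63-fold. Slc38a4 and Slc15a5, both of solute carrier families, were 1.62-fold and 1.60-fold lower, Neto2 1.53-fold and the surface glycoprotein gene Cd24a 1.53-fold.

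Of the 11544 probe sets tested, 359 passed an adjusted p of 0.05 (limma), 177 higher and 182 lower in heterozygous muscle, of which 340 carry a gene name here. With the replicate number as a block, 572 passed (262 higher, 310 lower), 339 of them among the 359. The median size of the called differences was 0.29 on the log2 scale, and 14 higher and 2 lower probe sets reached 1. The groups did not overlap at 3038 probe sets, 26.3% of those tested, against 10% by chance if all 6 mice are interchangeable, without pairing. Leaving out a mouse moved the count to 503, 121 and 84 without heterozygous mouse 1, 2 and 3, and to 97, 103 and 143 without wild-type mouse 1, 2 and 3. A set of 55 probe sets, 33 higher and 22 lower, passed with all 6 mice and in each of these fits, and it held Myh7, Tnnc1, Tnni1, Tnnt1, Ddit4, Ccn2, Arrdc2, 1700001O22Rik, Slc15a5, Neto2 and Cd24a. The other genes with the largest differences missed the threshold without at least 1 mouse, with adjusted p up to 0.054 for Cebpd, 0.114 for Mybph, 0.056 for Otud1, 0.106 for Odc1, 0.073 for Pfkfb3, 0.103 for Ucp3, 0.094 for Plin5, 0.097 for Slc38a4 and 0.063 for Smox. Mybph and Odc1 passed in only 1 of these 6 fits, and Ucp3 and Plin5 in 2. Without heterozygous mouse 1, the adjusted p of Odc1 was 5.79e-04.

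**Figure D1:**
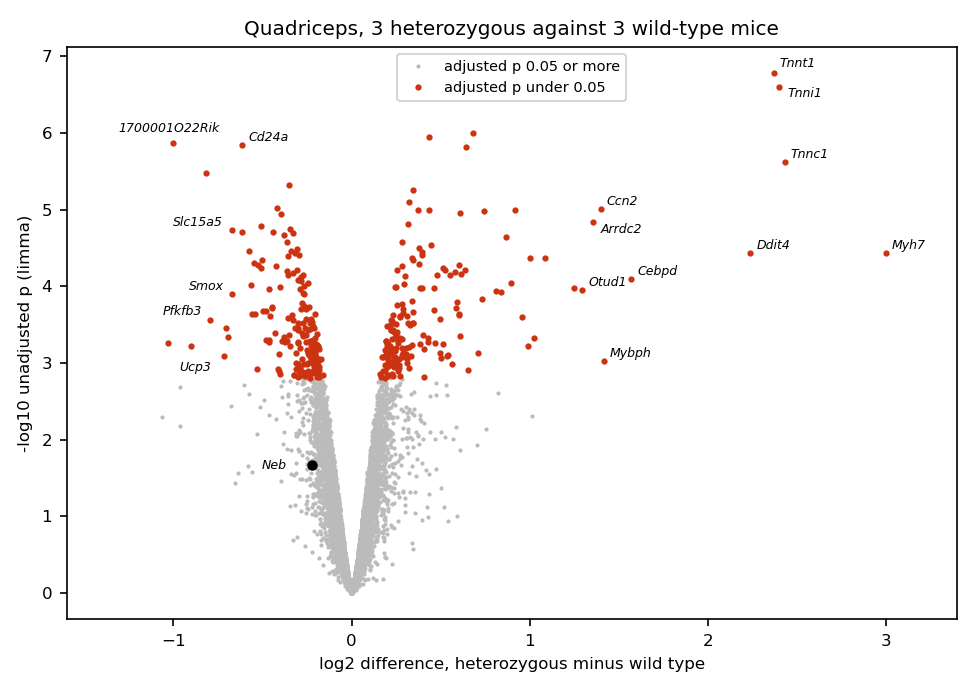
Log2 difference between heterozygous and wild-type quadriceps (x axis) against -log10 of the unadjusted limma p (y axis) for the 11544 tested probe sets, with those past an adjusted p of 0.05 in red and Neb in black. Of the 359 red points, 177 lie to the right, where Myh7, Tnnc1, Tnni1, Tnnt1 and Ddit4 stand apart at differences above 2.

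Of 13 slow fibre genes tested, 6 rose (Myh7, Tnnc1, Tnni1, Tnnt1 and the light chain genes Myl2 and Myl3), none fell and 7 did not pass; adjusted over the list alone, 10 rose. Myl2 and Myl3, bright in both genotypes, rose by 0.71 ± 0.14 and 0.60 ± 0.08 on the log2 scale (adjusted p = 0.035 and 0.012). Atp2a2, the slow-fibre calcium pump, had a difference of 0.82 ± 0.19 (adjusted p = 0.062, and 0.013 with the replicate block), Ankrd2 0.38 ± 0.12 (adjusted p = 0.12, and 0.042 with the block) and Csrp3 0.76 ± 0.21 (adjusted p = 0.098). Myh7b, at 6.79 and 6.84, had a difference of -0.04. The median difference of the list was 0.71, and it passed the list test (camera, adjusted p = 3.2e-10; adjusted p = 0.69 with an estimated correlation). The slow genes were variable between wild-type mice, and Myh7 measured 9.46, 7.88 and 9.29 in them against 12.35, 11.62 and 11.67 in heterozygous mice. Of 13 fast fibre genes none passed over all genes, and Tpm1 rose adjusted over the list alone (log2 difference 0.23, adjusted p = 0.067 over all genes). Myh4, the fastest myosin heavy chain, measured 13.17 ± 0.26 and 13.43 ± 0.15 (log2 difference -0.26 ± 0.12, adjusted p = 0.28), and the difference lay between -0.39 and -0.13 when a mouse was left out. The fast list had a median of 0.00, a mean of -0.01 and an upward list test with an adjusted p of 0.80. The fast genes Mylpf (14.55) and Pvalb (14.44) had the same value on all 6 arrays, among the brightest values of the shared distribution, and a difference in them was not measurable.

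**Figure D2:**
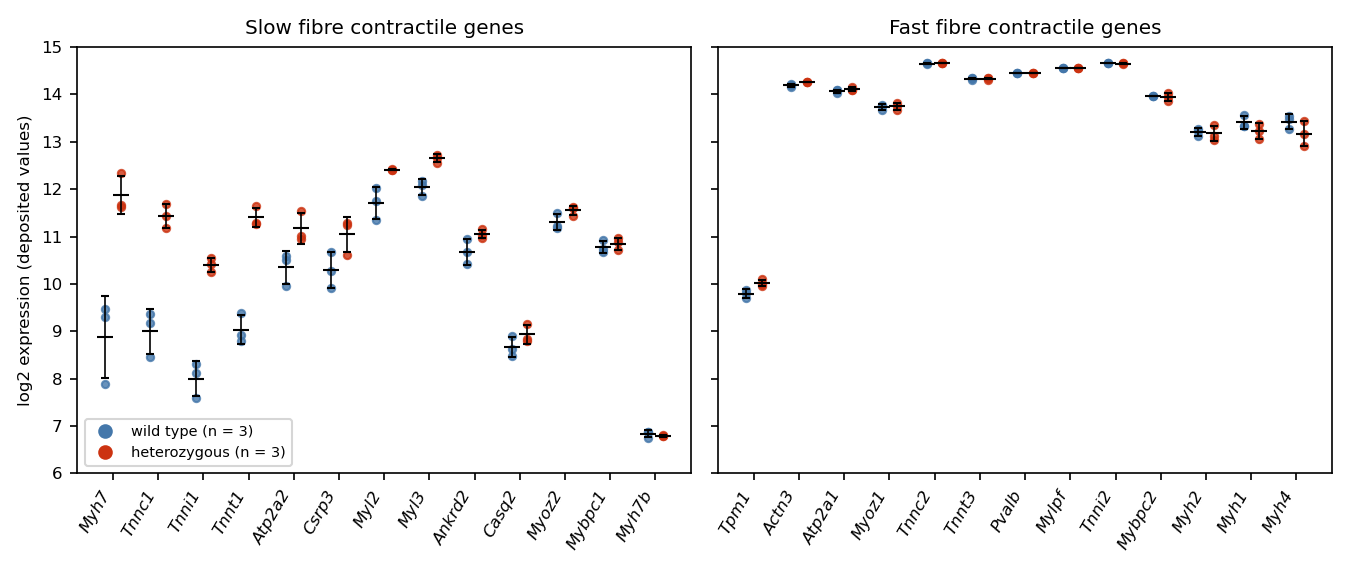
Deposited log2 expression (y axis) of 13 slow and 13 fast fibre genes (x axis) in each wild-type (blue) and heterozygous (red) mouse, with black bars for the mean and SD of 3 mice. Heterozygous mice lie above wild-type mice at Myh7, Tnnc1, Tnni1 and Tnnt1, and the fast genes other than Tpm1 all lie above 12 in both groups.

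Other sarcomere lists showed few changes. Of 13 nemaline myopathy genes tested, Tnnt1 rose and 12 did not pass, and the count adjusted over the list alone was the same (list test, adjusted p = 0.68). None of 16 genes of the thin filament and its length regulation passed over all genes, and 4 rose and 2 fell adjusted over the list alone. These included the capping protein gene Capzb (log2 difference 0.15, adjusted p = 0.063) and cardiac actin Actc1 (-0.57, adjusted p = 0.063, and 0.024 with the replicate block), with an adjusted p of 0.61 for the list. Among 20 Z-disc, titin and intermediate filament genes Fhl3 rose (0.24, adjusted p = 0.028), and 3 rose and 1 fell adjusted over the list alone, Myoz3 at -0.15 being the fall (list test, adjusted p = 0.11). Of 11 stretch and stress responsive genes none passed over all genes and 4 rose adjusted over the list alone, among them Ankrd23 (0.32, adjusted p = 0.084); the list gave an adjusted p of 0.064, and 0.044 with the block (adjusted p = 0.77 with the block and an estimated correlation). None of 23 genes of excitation-contraction coupling and calcium handling passed, over all genes or adjusted over the list alone, Cacng1 being among the closest (0.19, adjusted p = 0.091; list test, adjusted p = 0.16).

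Myog, a transcription factor of muscle differentiation, rose by 0.38 ± 0.07 on the log2 scale (adjusted p = 0.032), and it was the only call among 15 embryonic and regeneration genes. Adjusted over the list alone 3 of these rose and 1 fell, including Myod1 (0.35, adjusted p = 0.061 over all genes, and 0.037 with the replicate block); the list gave an adjusted p of 0.057, and 0.026 with the block (adjusted p = 0.77 with the block and an estimated correlation). Myog was also the only call, by either adjustment, among 15 denervation and neuromuscular junction genes, where Musk had a difference of -0.29 (adjusted p = 0.0997; list test, adjusted p = 0.61). Of 18 atrophy genes 4 rose, none fell and 14 did not pass; adjusted over the list alone 4 rose and 4 fell. The metallothionein genes Mt2 and Mt1 rose by 1.00 ± 0.13 and 0.41 ± 0.09, Foxo1 by 0.28 ± 0.05 and the cell cycle inhibitor gene Cdkn1a by 0.29 ± 0.06 (adjusted p = 0.011, 0.049, 0.031 and 0.035). The muscle ubiquitin ligase genes Trim63 and Fbxo32 had differences of 0.13 and -0.32 (adjusted p = 0.41 and 0.19), and the list had a median of -0.04, a mean of 0.06 and an upward test with an adjusted p of 0.94. The transcriptional coactivator genes Ppargc1a and Ppargc1b fell by 0.30 and 0.32 on the log2 scale (adjusted p = 0.040 and 0.027). They were the 2 falls among 16 growth and myostatin signalling genes, of which none rose; adjusted over the list alone 1 rose and 2 fell (list test, adjusted p = 0.37).

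Among 21 genes of fatty acid uptake and oxidation tested, 3 fell in heterozygous muscle, none rose and 18 did not pass, and all 21 differences were negative; adjusted over the list alone 9 fell. The fatty acid transporter gene Cd36 fell by 0.48 ± 0.09, Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, by 0.37 ± 0.07, and Ucp3 by 0.72 ± 0.14 (adjusted p = 0.032, 0.032 and 0.036). Pdk4, an inhibitor of pyruvate oxidation, had a difference of -0.96 ± 0.27 (adjusted p = 0.094) and Angptl4 of -0.64 ± 0.24 (adjusted p = 0.18, and 0.046 with the replicate block). The median of the list was -0.21 (camera, adjusted p = 5.8e-07; adjusted p = 0.69 with an estimated correlation). Of 16 glycolysis and glycogen genes, the glycogen synthesis genes Ugp2 and Gbe1 fell by 0.30 and 0.33 (adjusted p = 0.045 and 0.048), none rose and 14 did not pass; adjusted over the list alone 1 rose and 4 fell (list test, adjusted p = 0.075). Aldoa, among these 14, had the same value on all arrays, and a difference in it was not measurable. None of 37 oxidative phosphorylation genes passed by either adjustment: Ndufs4 had a difference of -0.20 (adjusted p = 0.071, and 0.036 with the block) and Cox6a1 of 0.19 (adjusted p = 0.10), and the list test gave an adjusted p of 0.37. None of 18 tricarboxylic acid cycle genes passed over all genes or adjusted over the list alone, with Mdh1 at -0.15 and Dlat at -0.14 (list test, adjusted p = 0.72).

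Clock genes changed in both directions. Of 15 tested, Per1, Nfil3, Per2 and Tef rose by 0.81 ± 0.12, 0.60 ± 0.10, 0.46 ± 0.07 and 0.17 ± 0.04 on the log2 scale, Arntl and Nr1d1 fell by 0.51 ± 0.06 and 0.41 ± 0.08, and 9 did not pass; adjusted over the list alone 8 rose and 3 fell. Their adjusted p ran from 0.0081 for Arntl to 0.045 for Tef, which reached 0.055 with the replicate block, and the list test gave an adjusted p of 0.066. Of 16 immediate early genes, which respond within minutes to stimulation, 5 rose, none fell and 11 did not pass; adjusted over the list alone 9 rose. Btg2, Nr4a1, Zfp36 and Klf4 rose by 0.52 ± 0.07, 0.50 ± 0.10, 0.54 ± 0.11 and 0.54 ± 0.11 (adjusted p = 0.012, 0.035, 0.036 and 0.035), and Ier3 by 0.31 ± 0.06. Fos and Egr1 did not pass, with differences of 0.12 and -0.30 that ranged from -0.12 to 0.45 and from -0.49 to -0.08 when a mouse was left out. The list had a median of 0.20 (camera, adjusted p = 1.9e-06; adjusted p = 0.69 with an estimated correlation). The chaperone gene Dnajb1 rose by 0.45 ± 0.05 (adjusted p = 0.010), the only call among 19 heat shock and chaperone genes, of which 2 rose and 2 fell adjusted over the list alone. Hsph1 of this list had a difference of -0.67 ± 0.17 (adjusted p = 0.071, and 0.0022 with the block; list test, adjusted p = 0.61).

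**Figure D3:**
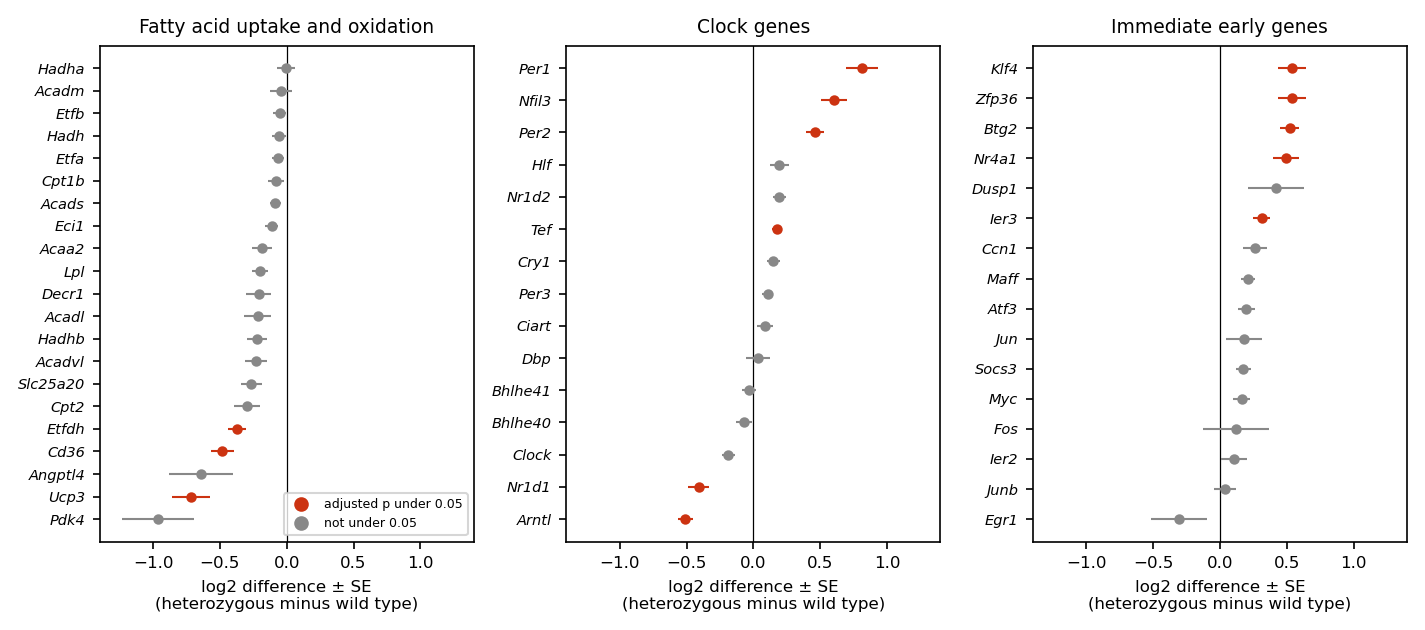
Log2 difference between heterozygous and wild-type muscle with its SE (x axis) for each tested gene (y axis) of 3 lists, in red where the adjusted p was under 0.05. All 21 fatty acid genes lie left of 0, 5 immediate early genes are red and higher, and the clock genes hold 4 red points to the right and 2 to the left.

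None of 22 proteasome subunit genes passed over all genes and 5 fell adjusted over the list alone, among them Psmd8 (-0.27, adjusted p = 0.064) and Psmd11 (-0.19, adjusted p = 0.089). The list had a median of -0.05 (camera, adjusted p = 0.035; adjusted p = 0.69 with an estimated correlation), and its call was lost without heterozygous mouse 3 (adjusted p = 0.17), without wild-type mouse 2 (0.12) and with cyclic loess (0.053). Of 10 cytosolic ribosomal protein genes none passed over all genes, and Rpl22 rose adjusted over the list alone (0.20, adjusted p = 0.080 over all genes, and 0.041 with the replicate block), with Rps15 at 0.19 (list test, adjusted p = 0.082).

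Markers of other cell types in the muscle changed little gene by gene. Beside Ccn2, the matrix gene Tnc rose by 0.43 ± 0.08 (adjusted p = 0.031); of 26 extracellular matrix genes these 2 rose and none fell, and 2 rose and 3 fell adjusted over the list alone (list test, adjusted p = 0.61). Loxl1, of the same list, had a difference of -0.34 (adjusted p = 0.053, and 0.0079 with the replicate block). All 8 tendon markers had positive differences, with Tnmd at 0.42 and Col11a1 at 0.32, and none passed by either adjustment. The tendon list had a median of 0.25 (camera, adjusted p = 0.014; adjusted p = 0.69 with an estimated correlation). Its call was lost without wild-type mouse 3 (adjusted p = 0.087). All 6 Schwann cell and nerve markers were likewise positive, none passing by either adjustment, with Mbp at 0.37 and Mal at 0.29 and a median of 0.19 (camera, adjusted p = 0.035; adjusted p = 0.69 with an estimated correlation). That call was lost without heterozygous mouse 1 (adjusted p = 0.14), without wild-type mouse 3 (0.10), with array weights (0.068) and with cyclic loess (0.053). The endothelial gene Egfl7 fell by 0.25 ± 0.04 (adjusted p = 0.027), the only call of 15 endothelial markers, of which 3 fell adjusted over the list alone. Kdr of this list had a difference of -0.25 (adjusted p = 0.057, and 0.017 with the block; list test, adjusted p = 0.090).

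Of 15 adipocyte markers only Cd36 fell, and 2 rose and 3 fell adjusted over the list alone, with Scd1 at 0.54 (adjusted p = 0.063; list test, adjusted p = 0.61). Tap1 rose by 0.19 ± 0.04 (adjusted p = 0.032), the only call by either adjustment of 11 interferon response genes, with Lgals3bp at -0.16 (list test, adjusted p = 0.61). No gene passed, over all genes or adjusted over the list alone, among 16 fibroblast markers (Islr -0.17 and Col1a1 0.39; list test, adjusted p = 0.26), 18 macrophage and leukocyte markers (Coro1a -0.13 and Adgre1 -0.12; adjusted p = 0.10) or 12 smooth muscle and pericyte markers (Lmod1 0.14 and Notch3 -0.10; adjusted p = 0.41). The macrophage list was called lower without heterozygous mouse 2 (adjusted p = 0.047) and without wild-type mouse 3 (3.34e-09; adjusted p = 0.68 in that fit with an estimated correlation). The endothelial list was called lower without heterozygous mouse 1 (0.0092) or wild-type mouse 3 (0.022), the fibroblast list higher without wild-type mouse 2 (0.010) and the smooth muscle list higher without heterozygous mouse 2 (0.017). With an estimated correlation in the same fits, the adjusted p was 0.70 and 0.68 for the endothelial, 0.84 for the fibroblast and 0.64 for the smooth muscle list, and 0.70 for the macrophage list without heterozygous mouse 2. Only 2 erythroid markers were measured above the filter, and neither passed.

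In all, 6 of the 30 lists passed the test with a preset correlation, and none did with an estimated correlation or with fry (smallest adjusted p 0.084, for the slow fibre genes). Without 1 mouse, 11 further lists passed in at least 1 fit, each in its direction with all mice: the 4 cell marker lists above and the Z-disc, stretch, embryonic, calcium handling, glycolysis, ribosomal protein and clock lists. None of these did with an estimated correlation (smallest adjusted p 0.64). At an unadjusted p the slow fibre list had 0.036 with an estimated correlation and 0.0028 by fry. Among the genes named from the lists, Tnnt1, Myl3, Mt2, Dnajb1, Btg2, Arntl and Ccn2 passed without any 1 of the mice. The calls of Cd36, Etfdh, Ucp3, Ugp2, Gbe1, Myog, Foxo1, Fhl3, Tnc, Tap1, Egfl7, Per2, Nr4a1, Ppargc1a and Ppargc1b were lost without at least 1 mouse, with adjusted p up to 0.147 for Gbe1. Most were lost in several of the 6 fits. Gbe1 passed in 0 of them, and Cd36, Etfdh, Ugp2, Tap1, Egfl7 and Ppargc1a in only 1 each. Myl2, Per1, Nfil3, Tef, Nr1d1, Mt1, Cdkn1a, Zfp36, Klf4 and Ier3 were likewise outside the 55 probe sets that passed in every fit. Of these genes, Mt1, Cdkn1a, Zfp36 and Ier3 passed in only 1 of the 6 fits. Leaving out a mouse also moved the difference over 1.5-fold for Tnmd (0.25 to 0.59), Col1a1 (0.22 to 0.55), Mbp (0.24 to 0.47), Mal (0.13 to 0.37), Rps15 (0.12 to 0.25), Lmod1 (0.06 to 0.19), Notch3 (-0.13 to -0.04), Coro1a (-0.19 to -0.09), Adgre1 (-0.18 to -0.07), Dlat (-0.17 to -0.08), Lgals3bp (-0.19 to -0.10), Eif2s3y (-0.54 to -0.18), Ankrd2 (0.25 to 0.51), Angptl4 (-0.84 to -0.33), Trim63 (0.03 to 0.22) and Myh7b (-0.09 to -0.02), none of them called with all mice. Ankrd2, Csrp3, Ankrd23, Psmd8, Psmd11, Myod1, Rpl22, Hsph1, Scd1, Kdr and Musk, not called with all mice, each passed in 1 of the 6 fits without a mouse.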

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

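The alternatives were chosen before the data were examined except cyclic loess, which was chosen after seeing them. The count of 359 probe sets became 572 with the replicate block, 870 at an adjusted p under 0.1 and 0 with Welch's test (1518 at an unadjusted p under 0.05), which estimates the spread of each probe set from its 3 and 3 values alone, and it ranged from 84 to 503 when a mouse was left out, with no called difference changing sign. It stayed between 321 and 483 with no filter, the 50th percentile filter, quantile normalization, median centring, an intensity trend, array weights and cyclic loess. Quantile normalization and median centring hardly move values that already share a distribution, and pseudocounts were not run because the values are log2. The Neb difference ranged from -0.31 to -0.13 when a mouse was left out. The 6 lists became 0 with an estimated correlation, 0 by fry, 8 with the block and 6 to 12 without a mouse; cyclic loess gave 4, losing the proteasome and nerve lists at an adjusted p of 0.053 each. The block changed no other call of a gene or list named in the text besides those given with it. Uty, with no call, ranged from -0.090 to 0.053 without a mouse. For the other genes named by the rule, results were tallied under alternatives with all mice, without Welch's test and the threshold of 0.1. Of these results, 581 stayed on their side of the threshold, 13 became past it and 2 were lost (Gbe1 at an adjusted p of 0.051 with an intensity trend, Ppargc1a at 0.057 with array weights). Under Welch's test no gene passed, and Tef, named after its value was seen, is outside this tally. The cause of these changes was not tested. Dim probe sets near the filter have less signal over background, so differences there are less certain.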

Other observations

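Genes known to be induced by glucocorticoids formed a group that was not among the lists fixed in advance. Some of its members were in those lists. Mt1, Foxo1, Trim63, Fbxo32 and Gadd45a were among the atrophy genes, and Dusp1 was among the immediate early genes. The rises of Mt1 and Foxo1 repeat the calls given above. Of 18 tested, 14 had a positive difference and 4 rose: the kinase gene Sgk1 by 0.52 ± 0.10 on the log2 scale, Mt1 by 0.41 ± 0.09, Map3k6 by 0.29 ± 0.05 and Foxo1 by 0.28 ± 0.05 (limma, adjusted p = 0.032, 0.049, 0.021 and 0.031). Fkbp5, a sensitive target of the receptor, had a difference of -0.05 (adjusted p = 0.66; -0.12 to -0.02 when a mouse was left out). The other negative differences were those of Fbxo32 (-0.32), Zbtb16 (-0.16) and Rgcc (-0.06), which did not pass (adjusted p = 0.19, 0.22 and 0.67). Of 5 lipid genes induced by fasting, Cpt1a fell by 0.36 ± 0.07 (adjusted p = 0.032), and Acot2 (-0.49, adjusted p = 0.067, and 0.0078 with the replicate block), Slc25a20 (-0.27, adjusted p = 0.10, and 0.022 with the block; -0.31 to -0.18 when a mouse was left out), Pdk4 and Angptl4 did not pass. Of 9 polyamine genes besides Odc1 and Smox none passed, with Sms at -0.20 and Azin1 at -0.16. Among heart muscle genes Mybpc3 rose by 0.25 ± 0.04 (adjusted p = 0.014). The calls of all 6 genes named here as changed were lost without at least 1 mouse, with adjusted p up to 0.103 for Sgk1, 0.141 for Mt1, 0.078 for Map3k6, 0.103 for Foxo1, 0.109 for Cpt1a and 0.056 for Mybpc3, and Sms passed in 1 of the 6 fits without a mouse.

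The gene patterns weighed here were chosen after their values were seen. The intervals of list medians come from resampling the genes of a list, not the mice, so they hold no spread between mice. The bounds of each test were written before its value was seen, except for the test of other splits by count of probe sets, which was chosen after its result was seen. The heart muscle test was widened, after its first value was seen, from the 5 genes above the filter to all 10 on the array, and it was judged after the values were seen by the rise heart RNA needed, since the bound of 0.1 set against it lies within the interval of its median.

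The higher slow fibre genes could come from more slow-twitch muscle in the sampled pieces, from a change within fibres or from heart muscle RNA. The 7 slow fibre genes used for this test had a median difference of 0.27 (95% bootstrap interval 0.07 to 0.76). It lies between the bound of 0.3 set for more slow-twitch muscle and the 0.1 set against it. These 7 are the members of the slow fibre list that did not pass, so leaving out the called members pulls the median down. They had also entered the list test. The test therefore cannot decide and leaves more slow-twitch muscle open. Higher expression within each fibre predicts the same rise. The 10 heart muscle genes had a median of 0.024 (interval -0.009 to 0.14), and the 5 above the filter 0.04 (interval -0.03 to 0.25), which argues against heart RNA, since it needed a median of at least 0.3. Myh6, the main myosin of the adult mouse heart, measured 6.03 in heterozygous and 6.02 in wild-type muscle, and the cardiac troponin gene Tnni3 6.63 and 6.64. A response of the fibres to the loss of a nebulin allele was not tested and stays open.

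Higher Per1, Ddit4 and Cebpd may reflect glucocorticoid exposure, a different time of day at sampling or fasting. The fasting-induced lipid genes argue against longer fasting in heterozygous mice. Their median was -0.49 (interval -0.96 to -0.27; camera p = 7.2e-05, p = 0.126 with an estimated correlation). Longer fasting needed at least 0.2, and 0.1 was set against it. Of these genes, Pdk4, Angptl4 and Slc25a20 also belong to the fatty acid list, whose differences were all negative. Their direction was therefore not new to this test. Only longer fasting in heterozygous mice was addressed. A difference in feeding in the other direction was not tested and stays open. The glucocorticoid-induced genes had a median of 0.16 (interval 0.04 to 0.29; camera p = 1.683e-04, p = 0.123 with an estimated correlation), short of the 0.2 set for the explanation and above the 0.1 set against it. For time of day, the bound followed the falls of Arntl and Nr1d1. The bound grouped clock genes by an assumed phase, that of Arntl or that of Nr1d1, which was not checked in these data. A fall under -0.2 was needed in both groups, and values above -0.1 in both were set against it. The 6 clock genes grouped with Nr1d1 had a median of 0.14, all positive, whereas Nr1d1 fell. They did not move with Nr1d1, so their rise is no evidence against a shift in time. Per1 and Per2, which rose, were in neither group. Only Clock and Cry1 could be measured of the genes grouped with Arntl (median -0.02), which is too few to decide. A shift in time that moves the phases in opposite directions was not covered by this bound, so the test leaves time of day open. Neither glucocorticoid exposure nor time of day can be told apart from an effect of genotype with these mice.

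Lower Odc1 and Smox suggest lower polyamine metabolism as a hypothesis. The 9 other genes of the pathway had a median of -0.032 (interval -0.16 to 0.09), with 2 of 9 positive, above the -0.05 set against a fall of the group but not by more than its spread, and short of the -0.1 set for it. The median therefore cannot decide. The set also pools enzymes of the pathway with regulators of it, which need not change in the same direction.

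The 6 mice can be split into equal groups in 10 ways, too few for a share under 0.05. Only the real split, 1 of 10, reached 359 probe sets, and the highest of the other splits gave 0. Each other split mixes the genotypes, so a genotype difference widens the spread within its groups and lowers its count. Of the 4 splits that part all same-numbered mice, the real one gave 572 with the replicate block and the others 0. For lists tested with the preset correlation, 9 of 10 splits had at least as many past the threshold as the real split, which had 6, and the highest other had 12. The median size of the slow fibre list was 0.71 in the real split and at most 0.38 in the others, whereas the fatty acid list reached 0.21 in both, the immediate early list 0.20 against 0.24 and the tendon list 0.25 against 0.28. The proteasome list had 0.05 against 0.04 and the nerve list 0.19 against 0.20. Lists that were not called could also be largest in the real split, such as the clock list (0.11 against 0.07). With the preset correlation, the slow fibre list was called in 6 of the other splits as well. Mixing the genotypes also shrinks a genotype difference in the medians of the other splits.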
